A study of Mus musculus with 9 samples.

How the data were processed

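RNA was measured in IMM cells, a line of immortalized mouse macrophages with the genotype given as WT, at 0, 30 and 60 min of lipopolysaccharide (LPS), with 3 libraries per time and 9 in all. LPS is an outer-membrane component of Gram-negative bacteria that macrophages sense through the receptor Tlr4. Per the labels, cells grew in a serum-containing medium, LPS was given at 100 ng/mL, dishes were put on ice at the end of each time, RNA was taken up with a column kit, and libraries were made with a stranded total RNA ligation kit that removes ribosomal RNA. Such libraries hold unspliced and non-polyadenylated RNA next to mature mRNA. The design text calls the 3 libraries of each time biological replicates and the 0 min libraries the control.

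The deposited table of the whole series holds expected counts per gene, estimated by the authors with RSEM, not normalized, for 55450 gene identifiers. Per the submitters' processing notes the tools were bcl2fastq 2.20, cutadapt 1.18, STAR 2.7.0f, Picard 2.18.26, RSEM 1.3.1 and DESeq2 with build mm10. The settings, the annotation and the strand setting of the counting are not given in the sources used here. RSEM shares reads that match several genes among them, so values of near-identical copies, such as histone and small nuclear RNA genes, are uncertain, as are those of overlapping genes. Between 5.04% and 5.32% of the values of a library were not whole numbers, and all were rounded before testing. The authors also deposited tables of their own DESeq2 comparisons for 30 and 60 min, which hold a log2 fold change, a p-value and an adjusted p-value per gene symbol, per the file headers. That 0 min is their baseline was read from the values. The model and filters behind these tables are not given in the sources used here, and they were set beside the values computed here only as the authors' own.

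Identifiers were matched to GENCODE M21 on GRCm38 (mm10), and 55450 of 55450 were found there. Gene classes, positions, introns and 3' untranslated regions come from that annotation. Positions are 1-based. Of 55450 genes, 31142 had 0 counts in every library. Where 2 identifiers shared a symbol in a gene list, the list took the identifier with the higher total count; 109 symbols were carried by more than 1 identifier.

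Library totals ran from 26867428 to 30402308 counts, and 13836 to 14021 genes reached 10 counts in a library. Levels are given as CPM, counts scaled to a common library total, and a count of 10 was worth about 0.35 CPM. CPM values use totals scaled by edgeR's TMM factors, which ran from 0.9705 to 1.034. Markers of cell identity, counted before the filter, are the exception: their CPM use the plain totals. Genes were kept by edgeR's filterByExpr with its defaults (a count of about 10 in 3 libraries), which left 14246 genes, 11313 of them protein-coding. Pairs of replicates differed by more than sampling noise, so no library is a copy of another. The mean chi-square per gene of a pair was 5.02 to 18.6, where sampling alone gives about 1. Loci with very many counts, such as Gm26917 and Gm42418, can carry much of this mean, so it does not describe a typical gene. That the libraries of a time are biological replicates rests on the labels alone.

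The comparisons were 30 min against 0 min, 60 min against 0 min and 60 min against 30 min, the last being the test of the difference between the effects at the later and the earlier time. All 9 libraries entered a single quasi-likelihood fit of edgeR 4.0.16 in R 4.3.3 with the time groups as the only term. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided, with no minimum fold; those changed at least 2-fold are counted separately. The SE of a log2 change was worked back from the gene test, as the absolute log2 change over the square root of the F statistic. The fitted spread between replicates was small (common dispersion 0.0027, a biological coefficient of variation of 5.2%). Genes were also sorted by their course. Transient genes were changed at least 2-fold at 30 min and then changed the other way by 60 min; held genes were changed at least 2-fold at 30 min with no further call; growing genes changed further the same way; late genes were not called in that direction at 30 min, were changed at least 2-fold at 60 min and were called from 30 to 60 min.

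The lists, 28 in all, cover macrophage responses, cell state and markers of other cell types. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at its preset correlation of 0.01, and p-values were adjusted over the 21 lists tested in a comparison. Where no correlation is named, a camera adjusted p is at this preset. Genes of a list can move together, and the estimated correlation of some called lists lay far above 0.01. For these the preset p-values overstate the strength of the result. Alternatives were camera with an estimated correlation and fry, which asks whether a list's own genes move on balance one way and compares them with no other genes. Member counts are given over all genes tested and adjusted over the list alone. The lists, the tests, the alternatives and the rule for named genes were set before the data were examined. The rule named, per comparison, the 10 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the 3 values of each group, passing over symbols of predicted or clone-named genes, then 14 fixed genes (Tnf, Il1b, Il6, Cxcl2, Ccl3, Ccl4, Nfkbia, Tnfaip3, Fos, Egr1, Ifnb1, Ptgs2, Tlr4, Nos2) and, per list, up to 4 members with the smallest adjusted p. Among the falls, 23, 19 and 22 clone-named genes were passed over at 30 min, 60 min and from 30 to 60 min, and among the rises 0, 0 and 1. List members named outside this rule, where a count is small, were chosen after their values were seen. Some genes that the rule names are not reported here, while counts of genes and list members include them.

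Where a group held 1 to 3 counts over its 3 libraries, the ratio of summed counts is given with an exact 95% interval, and where it held 0 counts, a lower bound set against 3 counts over the group. Sequenced reads are not independent molecules, so these intervals and bounds cover counting error only.

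The gene test was tested on simulated counts drawn from the real means and library sizes of 14246 genes with 200 changed genes. At true folds of 1.5, 2 and 4 it recovered 71.6%, 77.6% and 87.9% of them in the setting of 30 min against 0 min (9 unchanged genes called), 71.6%, 82.1% and 97% in that of 60 min against 0 min (14 unchanged genes called), and 71.6%, 85.1% and 97% in that of 60 min against 30 min (11 unchanged genes called). With 25 simulated genes per course, 22 to 25 were returned in their own class. These genes all had a mean above 1 CPM and changed 4-fold or more, while the real classes start at 2-fold. Return to the right class at smaller folds or lower levels was not tested. Other genes entered some classes, with 7 in held lower, 2 in transiently lower, 2 in late lower, 1 in held higher and 0 in the rest. In simulated lists over the same 14246 genes, 4 of 4 raised lists were called at 60 min and again from 30 to 60 min. Of the other lists 0 were called at 30 min, 0 at 60 min and 3 from 30 to 60 min, where 21 lists were tested. The simulated genes were drawn independently of each other, so false calls of lists whose genes move together were not tested.

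Alternatives were DESeq2 size factors in place of TMM, total counts only, no filter on low counts, a minimum count of 50, removal of structural RNA genes, the replicate number as a block, only the groups compared in the fit, a test against a fold of 1.5, the Wald test of DESeq2 1.42.0, limma-voom, and leaving out each library in turn. The structural RNA genes removed include all mitochondrial genes, protein-coding ones too, and the loci Gm26917 and Gm42418. No column of the table of the whole series was left unused.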

Results

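Total RNA was sequenced from immortalized mouse macrophages (IMM) before LPS (0 min, the control) and at 30 and 60 min of 100 ng/mL LPS, in 3 libraries per time, to follow how gene expression changes in the first hour. The series holds no library without LPS at 30 or 60 min. LPS, handling and time therefore changed together, and their effects cannot be told apart. Libraries held 26867428 to 30402308 counts. Macrophage genes were abundant at 0 min, with means (CPM by plain totals) of 578 CPM for Csf1r, the receptor for macrophage colony-stimulating factor. The mean was 441 CPM for the lysosomal protein gene Cd68, 399 CPM for the lysozyme gene Lyz2, 165 CPM for Itgam and 131 CPM for Adgre1. Protein-coding genes took 82.9% to 84.9% of the counts of a library, mitochondrial genes 3.32% to 4.28%, and the loci Gm26917 and Gm42418, which carry ribosomal RNA sequence, 7.81% to 8.88%. Structural RNA genes, a set that here includes all these mitochondrial genes and the loci Gm26917 and Gm42418, took 14.5% ± 0.458 (SD, n = 3) at 0 min. They took 14.6% ± 0.473 at 30 min and 15.4% ± 0.551 at 60 min.

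The first principal component of the log2 CPM values, with 44.2% of the variance, ordered the libraries by time. The 0 min libraries lay at -33.3, -34.8 and -31.6, the 30 min libraries at 9.2, 0.2 and 1.5, and the 60 min libraries at 31.7, 29.1 and 27.9. The second component, with 16.6%, set the 30 min libraries apart from both other times. Of the 30 min libraries, replicate 1 lay closest to the 60 min libraries on the first component.

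**Figure D1:**
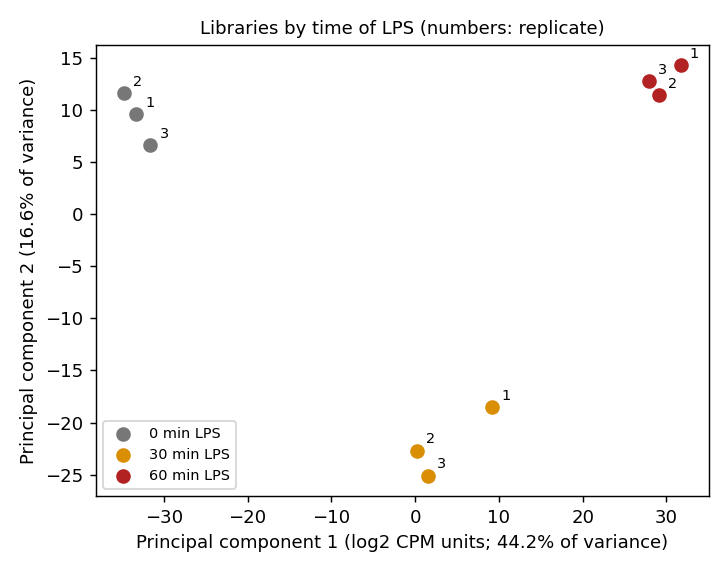
Each point is 1 of the 9 libraries, placed by its first and second principal components of log2 CPM, coloured by minutes of LPS and numbered by replicate. The 3 times separate, and replicate 1 of 30 min lies at 9.2 on the first component against 0.2 and 1.5 for the other 30 min libraries.

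Genes of the fixed lists of other cell types were low. By plain totals, the highest group mean of any member was 0.211 CPM for fibroblast, 0.0233 CPM for epithelial, 0.27 CPM for B cell and 0.801 CPM for endothelial markers, and mast cell markers had 0 CPM throughout. It was 3.62 CPM for the T cell markers, reached by the kinase gene Lck, 6.08 CPM for the neutrophil markers, reached by the receptor gene Csf3r, and 8.86 CPM for the dendritic cell markers, reached by Batf3. Neither Lck nor Csf3r was called in any of the 3 comparisons, nor were the tested endothelial markers Pecam1 and Kdr. Adjusted over its list alone, where it is the only tested member, Lck fell from 30 to 60 min (log2 change -0.33). Of 4 tested dendritic cell markers, 0 rose and 0 fell at 30 min by edgeR (0 at an unadjusted p under 0.05, and 0 by DESeq2 or limma-voom). At 60 min 0 rose and 2 fell, Zbtb46 by a log2 change of -0.31 and Xcr1 of -1.88. The call of Zbtb46 at 60 min was lost with DESeq2 (adjusted p = 0.0768) and without 0 min replicate 1, 60 min replicate 1 or 60 min replicate 3 (0.0524 to 0.0669). That of Xcr1 was lost with DESeq2 (0.0825) and without any library but 0 min replicate 1 and 60 min replicate 2 (0.054 to 0.15), and its log2 change was -3.35 without the latter. From 30 to 60 min 0 rose and Zbtb46 fell (-0.37), and the list was not called in any comparison (camera adjusted p = 0.976 at 30 min, 0.442 at 60 min and 0.257 from 30 to 60 min).

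The comparison of 30 min with 0 min asks which transcripts had changed at the earlier time. Cxcl2, a chemokine that attracts neutrophils, rose from 0.37 ± 0.042 to 145 ± 36 CPM (SD, n = 3 per time), the largest rise of this comparison among genes above 5 CPM. Il1b, which encodes the precursor of interleukin-1 beta, rose 168-fold, from 0.25 ± 0.098 to 43.4 ± 22.6 CPM, with 69.2 CPM in replicate 1 against 27.5 and 33.5 CPM in the other 30 min libraries. The AP-1 genes Fosb and Fos rose 80.9-fold and 26.9-fold, and the inhibitors of NF-kB signalling Tnfaip3 and Nfkbia rose 24.4-fold (6.07 ± 0.705 to 148 ± 41.8 CPM) and 8.86-fold (19.0 ± 0.847 to 168 ± 35.9 CPM). Txnip, a thioredoxin-binding protein that restrains glucose uptake, fell 2.1-fold, from 194 ± 8.89 to 92.6 ± 11.6 CPM.

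Of 14246 genes tested with edgeR, 689 were higher and 477 lower at 30 min, 201 and 59 of them by at least 2-fold. The median absolute log2 fold change of the called genes was 0.5 for the higher and 0.44 for the lower. Of the 201 genes higher by at least 2-fold, 125 were protein-coding, against 9 of the 59 lower genes. Loci of every class other than protein-coding thus made up 84.7% of the lower set and 37.8% of the higher set, and of these 50 lower loci 22 were annotated as TEC, a class of loci still awaiting an experimental check. The lower set had a median of 0.947 CPM against 7.18 CPM for the higher set. Without 0 min replicate 1, 30 min replicate 2 or 30 min replicate 3, the lower genes numbered 290, 310 and 305. Tested against a fold of 1.5, 180 genes were higher and 28 lower, and with total counts as the only scaling the split turned to 551 higher and 649 lower (45.9% higher, against 59.1% with TMM and 57.4% with DESeq2 size factors).

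The largest rises also included Ccrl2, an atypical chemoattractant receptor (49.4-fold), the nuclear receptor gene Nr4a2 (34.1-fold), the TNF receptor adaptor gene Traf1 (28.6-fold), the inhibitor of DNA binding Id3 (27.1-fold) and Thbs1, which encodes thrombospondin-1 (24.5-fold). Their log2 fold changes ran from 4.62 with SE 0.24 for Thbs1 to 5.63 with SE 0.22 for Ccrl2. The 0 min libraries held 9, 4 and 20 counts of Traf1 and 15, 68 and 19 of Id3. Without 0 min replicate 3 the log2 change of Traf1 was 5.53 in place of 4.84, and without 0 min replicate 2 that of Id3 was 5.77 in place of 4.76. For Cxcl2 (ENSMUSG00000058427.10, chromosome 5, 90903871 to 90905938, plus strand of GRCm38) the log2 change was 8.60 with SE 0.25 (edgeR adjusted p = 2.53e-11). For Il1b (ENSMUSG00000027398.13, chromosome 2, 129364570 to 129371139, minus strand) it was 7.39 with SE 0.55 (edgeR adjusted p = 4.57e-07). The largest falls were those of the histone gene Hist2h3c1 (7.31-fold, uncertain because near-identical histone genes can share reads) and Txnip (ENSMUSG00000038393.14, chromosome 3, 96557957 to 96561883, plus strand; log2 change -1.07, SE 0.07, edgeR adjusted p = 7.86e-08). They were followed by the antisense gene Ttc39aos1 (1.91-fold), the ribosomal protein copy Rps12l1 (1.73-fold) and the snoRNA host genes Zfas1 (1.73-fold) and Snhg5 (1.6-fold). Rps12l1 (edgeR adjusted p = 0.0328) lost its call with DESeq2 and without 0 min replicate 1 or 3 or any of the 30 min libraries, where its adjusted p ran from 0.0519 to 0.154.

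Fixed-list cytokines and chemokines rose together at 30 min. Of 18 tested cytokine genes 13 rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 4.36e-42). Tnf rose 7.19-fold from 47.5 ± 4.27 to 341 ± 91.4 CPM, and Osm, Tnfsf9 and the angiogenic factor Vegfa had log2 changes of 3.5, 1.81 and 1.09. Il6 had 3 counts over the 0 min libraries and 151 at 30 min, a ratio of 51.2 (95% counting interval 17.2 to 251). The fitted log2 change of Il6, which depends on the prior count, moved from 5.51 to 6.32 without 0 min replicate 3. Of 10 tested chemokine genes 6 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 1.77e-34), with log2 changes of 3.7 for Cxcl10, 1.46 for Ccl4, 0.83 for Ccl2 and 0.62 for Ccl3. Of 23 inflammatory effector genes 15 rose and 0 fell (17 and 0 adjusted over the list alone; camera adjusted p = 4.83e-25). Among them Ptgs2, the inducible cyclooxygenase, rose 11-fold from 7.23 ± 1.74 to 79.0 ± 16.1 CPM, and the lectin receptor Clec4e and the serum amyloid gene Saa3 had log2 changes of 3.11 and 3.12. Nos2, the inducible nitric oxide synthase, had 12 counts at 0 min and 39 at 30 min. Its call (edgeR adjusted p = 0.035) was lost with DESeq2 (0.0558) and limma-voom (0.0504), and without any of the 0 min libraries or 30 min replicate 1 or 2 (0.0646 to 0.131).

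Transcription and feedback regulators rose with them. Of 27 immediate-early transcription factor genes 23 rose and 0 fell (23 and 0 adjusted over the list alone). The camera adjusted p was 3.82e-200 at the preset correlation and 0.000354 at the estimated correlation of 0.261. Btg2 had a log2 change of 3.55 and Junb of 2.08, beside Fosb and Fos. The list's median log2 change was 1.39, also with Myc set at its bound: Myc had 0 counts at 0 min and 22 at 30 min, at least 7.45-fold higher. Egr1 had 18 counts at 0 min and 34 at 30 min and was not called (edgeR adjusted p = 0.46). Of 19 genes for NF-kB subunits and inhibitors 13 rose and 0 fell (14 and 0 adjusted over the list alone), including Nfkbiz at 3.48 and Tnip3 at 2.13. The camera adjusted p of this list was 2.8e-42 at the preset correlation and 0.0134 at the estimated correlation of 0.586. Of 22 signalling and mRNA-decay feedback regulators 13 rose and 1 fell (17 and 1 adjusted over the list alone; camera adjusted p = 1.66e-42). The phosphatase genes Dusp1 and Dusp5 had log2 changes of 4.21 and 2.53, Zfp36, which binds AU-rich elements of mRNAs, 3.3, and Socs3, an inhibitor of cytokine signalling, 3.05, and the member that fell was the phosphatase gene Dusp6 (-0.29). Of 24 short-lived growth and signalling regulators 11 rose and 1, Txnip, fell (15 and 2 adjusted over the list alone; camera adjusted p = 8.82e-19), with Pim1 at 2.47, Cdkn1a at 2.28 and Trib1 at 1.92.

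Of 15 ATF4 and unfolded protein response genes 10 rose and 0 fell (12 and 0 adjusted over the list alone; camera adjusted p = 3.24e-12), among them Ppp1r15a at 1.58, Ddit4 at 0.9 and Slc7a11 at 0.6. Of 19 glycolysis and hypoxia response genes 9 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p = 1.19e-05, and adjusted p = 0.118 with an estimated correlation). The largest changes there were those of Hilpda, a lipid droplet protein (1.61), and the mitophagy gene Bnip3 (0.66). Of 28 TLR pathway components 3 rose and 1 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.0207, adjusted p = 0.0913 with an estimated correlation, and 0.0731 without 0 min replicate 2). Cd14 and Tlr2 had log2 changes of 1.99 and 1.58 and Map3k8 of 0.56. Tlr9 fell (-0.28), a call lost with the adjusted p at 0.0645 to 0.128 without 0 min replicate 1 or any of the 30 min libraries. Tlr4, the LPS receptor, stood at 90.1 ± 5.45 and 93.0 ± 1.19 CPM and was not called (edgeR adjusted p = 0.631).

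The other lists were not called at 30 min by camera. Of 25 type I interferon and interferon-stimulated genes 2 rose and 1 fell (camera adjusted p = 0.199 for the list, and 0.0279 without 0 min replicate 3). Irf1 (1.45) and Rsad2 (1.15) rose and Stat2 (-0.38) fell. Ifnb1 had 0 counts at 0 and 30 min and 4 at 60 min and was below the filter. Of 13 inflammasome and pyroptosis genes 1, Nlrp3 (1.87), rose and 0 fell. Mefv, with 1 count at 0 min and 14 at 30 min (ratio 14.2, 95% counting interval 2.17 to 602), had a log2 change of 3.41 (edgeR adjusted p = 0.0785). It was called with limma-voom (0.0369) and with no filter on low counts (0.00977), so in those fits it does not count as late. Aim2 (-0.13, edgeR adjusted p = 0.104) was called lower with total counts as the only scaling (0.0488), with no filter on low counts (0.0259) and without 0 min replicate 2 (0.0493). The list had a camera adjusted p of 0.052, and of 0.0244, 0.00624 and 0.0257 without 30 min replicate 1, 2 or 3, 0.0476 with total counts as the only scaling and 0.00778 with no filter on low counts. Of 13 regulatory non-coding RNA genes 3 rose and 2 fell (camera adjusted p = 0.0878, 0.0341 without 30 min replicate 2 and 0.0369 with no filter on low counts). Neat1 was at 0.57, Ptgs2os2 at 1.16, Gas5 at -0.51 and Snhg12 at -0.53. Mir155hg rose from 2 counts at 0 min to 103 at 30 min, a ratio of 52.4 (95% counting interval 14.1 to 438). Of 21 macrophage identity genes 2 rose and 1 fell (camera adjusted p = 0.116). Cebpb was at 0.88, while Maf at -0.19 lost its call without some libraries of 0 and 30 min. Of 17 homeostatic macrophage receptors 0 rose and 1, Trem2 (-0.32), fell (camera adjusted p = 0.86 for the list). Of 16 cholesterol synthesis and uptake genes 3 rose (camera adjusted p = 0.119), among them Insig1 (0.41) and Srebf2 (0.12, lost without any single library). Heat shock proteins (0 of 11 called; camera adjusted p = 0.976), oxidative phosphorylation (0 of 19; 0.285) and mitotic cell cycle genes (0 of 19; 0.673) had no member past the gene test of edgeR. At an unadjusted p under 0.05 they had 1 higher and 1 lower, 1 and 0, and 3 and 2, and by DESeq2 or limma-voom 0 were called. Calls were gained by Plk1 (-0.1) with total counts as the only scaling (0.0164), at a minimum count of 50 (0.0348) and without 60 min replicate 3 (0.0455), and by Hspa5 (0.12) without 0 min replicate 2 (0.0454). The identity gene Ctsd (0.1) gained a call with DESeq2 (0.0416). Of 18 DNA replication genes 0 rose and 1 fell (camera adjusted p = 0.976 for the list). It was Tyms (-0.15), whose call was lost without 0 min replicate 3 or 30 min replicate 2. By fry the cholesterol (adjusted p = 0.000471), identity (0.00155), inflammasome (0.00662) and non-coding RNA (0.0422) lists were called. Adjusted over the list alone, the counts were the same but for the inflammasome genes (3 higher and 1 lower), the non-coding RNA genes (6 and 3) and the cholesterol genes (5 and 0).

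**Figure D2:**
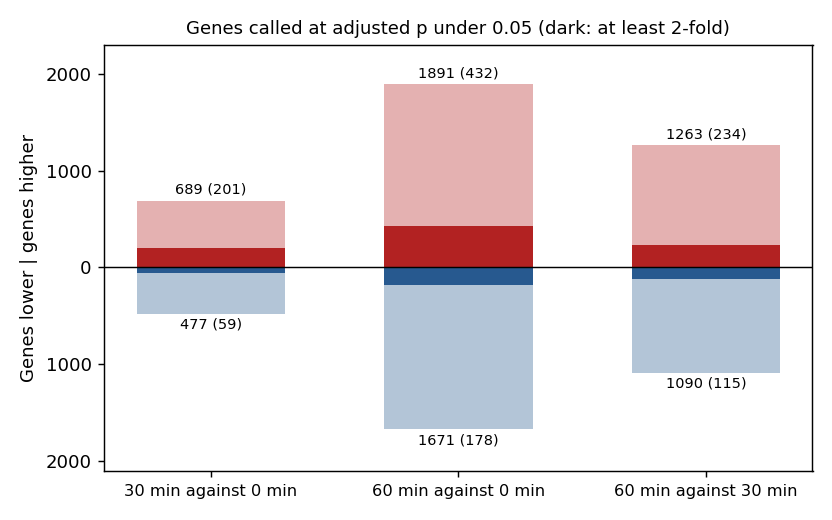
Bars give the number of genes called higher (red, upward) or lower (blue, downward) by edgeR in each comparison, with the part changed at least 2-fold in the darker shade and in brackets. At 60 min 1891 genes were higher and 1671 lower than at 0 min, against 689 and 477 at 30 min.

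The comparison of 60 min with 0 min asks which transcripts had changed by the end of the hour. Cxcl2 was 694-fold higher (260 ± 18.1 CPM), Il1b 420-fold (109 ± 17.8 CPM), Tnf 11.8-fold (560 ± 37.5 CPM), Nfkbia 20.6-fold (390 ± 7.16 CPM) and Tnfaip3 44.8-fold (271 ± 17.2 CPM; SD, n = 3). Acod1, which makes the metabolite itaconate, rose 81.2-fold, from 1.64 ± 0.357 to 134 ± 13.4 CPM. Dusp6, a phosphatase for ERK kinases, fell 2.65-fold, from 78.6 ± 4.41 to 29.6 ± 2.94 CPM, and Txnip fell 2.27-fold.

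With edgeR, 1891 genes were higher and 1671 lower at 60 min, 432 and 178 of them by at least 2-fold; the median absolute log2 fold change was 0.38 and 0.35. Of the genes changed at least 2-fold, 284 of the higher and 49 of the lower were protein-coding, so other loci made up 34.3% of the higher and 72.5% of the lower set. The split depended on the scaling. With total counts alone 1313 genes were higher and 3048 lower (30.1% higher, against 53.1% with TMM and 52.5% with DESeq2 size factors), while the median log2 change of all genes moved to -0.07. The TMM factors averaged 1.022 at 0 min, 1.004 at 30 min and 0.9748 at 60 min. Tested against a fold of 1.5, 430 genes were higher and 102 lower.

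Of the 689 genes higher at 30 min, 566 (82.1%) were also called higher at 60 min and 6 were called lower, where independent lists of these sizes share 91.5. Of the 477 lower at 30 min, 285 (59.7%) were also lower and 6 were higher at 60 min, where independent lists share 56. At an unadjusted p under 0.05, 1127 genes were higher and 812 lower at both times, where 20 simulations of unchanged groups with a shared control gave 53 to 97 and 53 to 74. The simulations held no changed genes, so they do not show how much a shared control adds among genes that do change. The 3 control libraries are too few to split, so part of the excess may come from the shared controls.

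The next largest rises at 60 min were those of Traf1 (148-fold), the nuclear receptor gene Nr4a3 (112-fold), Ccrl2 (90.6-fold), the activation antigen Cd69 (76.2-fold), Fosb (70.6-fold) and Id3 (60.9-fold). Mir155hg, the host gene of microRNA miR-155, had 2 counts at 0 min, and its ratio of summed counts was 249 (95% counting interval 68.7 to 2060). The log2 changes of Traf1, Cd69 and Id3 were 7.21, 6.25 and 5.93, and 7.91, 7.39 and 6.93 without 0 min replicate 3 for Traf1 and 0 min replicate 2 for the others. The largest falls after Hist2h3c1 (5.12-fold, uncertain as above) and Dusp6 (ENSMUSG00000019960.8, chromosome 10, 99263231 to 99267489, plus strand; log2 change -1.41, SE 0.07, edgeR adjusted p = 1.54e-09) were those of Txnip and Ttc39aos1 (2.22-fold). Next were the zinc finger gene Zswim3 (2.12-fold) and Stat2, a transducer of interferon signals (2.09-fold, from 14.6 ± 0.89 to 7.01 ± 0.325 CPM). Fos was 7.79-fold higher than at 0 min, at 56.8 ± 13.2 CPM. Ptgs2 was 15.3-fold higher, Ccl4 5.46-fold, Ccl3 2.08-fold and Nos2 11.3-fold, from 12 counts to 141. Il6 had 219 counts, a ratio of 72.2 to the 3 counts at 0 min (95% counting interval 24.4 to 353). Its fitted log2 change moved from 6.01 to 6.81 without 0 min replicate 3. Egr1 (36 counts, edgeR adjusted p = 0.314) and Tlr4 (84.4 ± 3.72 CPM, edgeR adjusted p = 0.154) were not called. Egr1 was called without 60 min replicate 1 (log2 change 1.49), and Tlr4 with total counts as the only scaling (-0.16).

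At 60 min most members of the inflammatory lists were higher. Of 27 immediate-early transcription factor genes 25 rose and 0 fell (25 and 0 adjusted over the list alone; camera adjusted p = 8.61e-108). Junb had a log2 change of 2.81, Btg2 of 3.37 and Klf6 of 1.32, and the median was 1.39, also with Myc at its bound of at least 16.2-fold (0 counts against 49). Of 19 genes for NF-kB subunits and inhibitors 18 rose and 0 fell (18 and 1 adjusted over the list alone; camera adjusted p = 7.15e-76), including Nfkbiz at 4.82 and the subunit gene Nfkb1 at 0.98. Of 22 feedback regulators 18 rose and Dusp6 fell (19 and 1 adjusted over the list alone; camera adjusted p = 1.79e-45), including Dusp1 at 4.06, Dusp5 at 3.8, the ribonuclease gene Zc3h12a at 2.6 and its relative Zc3h12c at 1.66. Of 18 cytokine genes 15 rose and 0 fell (15 and 0 adjusted over the list alone; camera adjusted p = 1.95e-35), with Csf1 at 2.55, Osm at 2.96 and Tnfsf9 at 2.76. Of 10 chemokine genes 9 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 1.07e-33), with Cxcl10 at 5.65 and Ccl2 at 1.4. Of 23 inflammatory effector genes 20 rose and 0 fell (21 and 0 adjusted over the list alone; camera adjusted p = 5.21e-45), with Clec4e at 4.06 and the urokinase gene Plau at 1.72. Of 24 short-lived growth and signalling regulators 14 rose and 6 fell (14 and 7 adjusted over the list alone; camera adjusted p = 5.87e-15). Pim1 was at 3.56, Gadd45a at 3.06, Cdkn1a at 2.68 and Trib1 at 2.66 among the rises, and Rgs2 at -0.56, Tsc22d3 at -0.54 and Sesn1 at -0.51 among the falls.

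TLR pathway components went both ways at 60 min. Of 28, 10 rose and 6 fell (12 and 7 adjusted over the list alone; camera adjusted p = 8.36e-05, and adjusted p = 0.0153 with an estimated correlation). Cd14 at 2.61, Tlr2 at 2.58, Map3k8 at 1.53 and the kinase gene Irak2 at 1.47 rose, and Tlr1 (-0.31), Tlr7 (-0.22) and the adaptor genes Tirap (-0.31) and Ticam2 (-0.31) fell. Of 13 inflammasome and pyroptosis genes 5 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.00316, and adjusted p = 0.101 with an estimated correlation). The test was upward with a mean log2 change of 0.79 while the median was -0.04. The members that rose were Nlrp3 (2.96), Casp4 (1.55), Ninj1 (0.39), Nlrc4 (0.19) and Mefv, which had 1 count at 0 min and 89 at 60 min, a ratio of 88.1 (95% counting interval 15.4 to 3520). The fitted log2 change of Mefv, which depends on the prior count, was 6 and moved to 7.89 without 0 min replicate 1 and to 5.32 with limma-voom. Of 15 ATF4 and unfolded protein response genes 11 rose and Xbp1 (-0.29) fell (12 and 1 adjusted over the list alone; camera adjusted p = 3.74e-08, and adjusted p = 0.0603 with an estimated correlation). Slc7a11 was at 1.54, Ppp1r15a at 1.56 and Herpud1 at 0.74. Of 19 glycolysis and hypoxia response genes 9 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 0.00242, and adjusted p = 0.274 with an estimated correlation). Hilpda was at 1.93 and the glucose transporter gene Slc2a1 at 0.61. Of 13 regulatory non-coding RNA genes 6 rose and Gas5 (-0.35) fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0217, adjusted p = 0.37 with an estimated correlation, and 0.0523 without 60 min replicate 1). Mir22hg was at 1.55, Ptgs2os2 at 0.87 and Mir17hg at 0.62.

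The interferon list was not called at 60 min. Of 25 tested members 3 rose and 3 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.656). Irf1 (2.72), Rsad2 (1.25) and Ifi204 (0.28) rose, and Stat2 (-1.06), Irf8 (-0.29) and Ifit2 (-0.24) fell. Of 19 mitotic cell cycle genes 0 rose and 6 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.0909, 0.0434 without 60 min replicate 3, 0.0125 with total counts as the only scaling and 0.0444 with no filter on low counts). The amounts were small, as for Plk1 (-0.22), Aurka (-0.2), Cenpf (-0.18) and Bub1b (-0.15). Of 21 macrophage identity genes 5 rose and 2 fell (camera adjusted p = 0.442), with Cebpb at 1.3, Csf1r at 0.19 and Maf at -0.57. Of 17 homeostatic macrophage receptors 2 rose and 2 fell (camera adjusted p = 0.929). The scavenger receptor gene Stab1 (0.7) and Tgfbr1 (0.21, lost without 0 min replicate 1 or 60 min replicate 1) rose, and Trem2 (-0.47) was among those that fell. Of 18 DNA replication genes 4 rose and 2 fell (camera adjusted p = 0.735), with Cdt1 at 0.2 and Cdc6 at -0.18. Of 16 cholesterol genes 3 rose and 1 fell (camera adjusted p = 0.766), with Insig1 at 0.43, Srebf2 at 0.23 and Sc5d at -0.19. Heat shock proteins (1 of 11 rose and 1, Hsph1 at -0.13, fell) and oxidative phosphorylation genes (1 of 19 rose) were not called as lists (camera adjusted p = 0.735 and 0.533). By fry the identity (adjusted p = 0.00135), mitotic (0.00356), DNA replication (0.00356), cholesterol (0.0091), oxidative phosphorylation (0.0422) and dendritic cell (0.0422) lists were called. The single rises of the heat shock and oxidative phosphorylation lists, Bag3 at 0.13 and Cox6a1 at 0.12, lost their calls with DESeq2 and without any of the 0 min libraries. Hspa5 (0.15, edgeR adjusted p = 0.0522) was called in 6 alternatives, among them DESeq2 (0.0116) and limma-voom (0.0393), and Hspe1 (-0.09) with total counts as the only scaling (0.00912). Ndufv1 (0.16) was called with no filter on low counts (0.0309) and without 0 min replicate 3 (0.0188) or 30 min replicate 2 (0.0473), and Uqcrc1 (0.09) without 0 min replicate 3 (0.031). Adjusted over the list alone, the counts were the same but for the identity genes (6 higher and 3 lower), the heat shock proteins (2 and 1) and the oxidative phosphorylation genes (0 and 0).

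**Figure D3:**
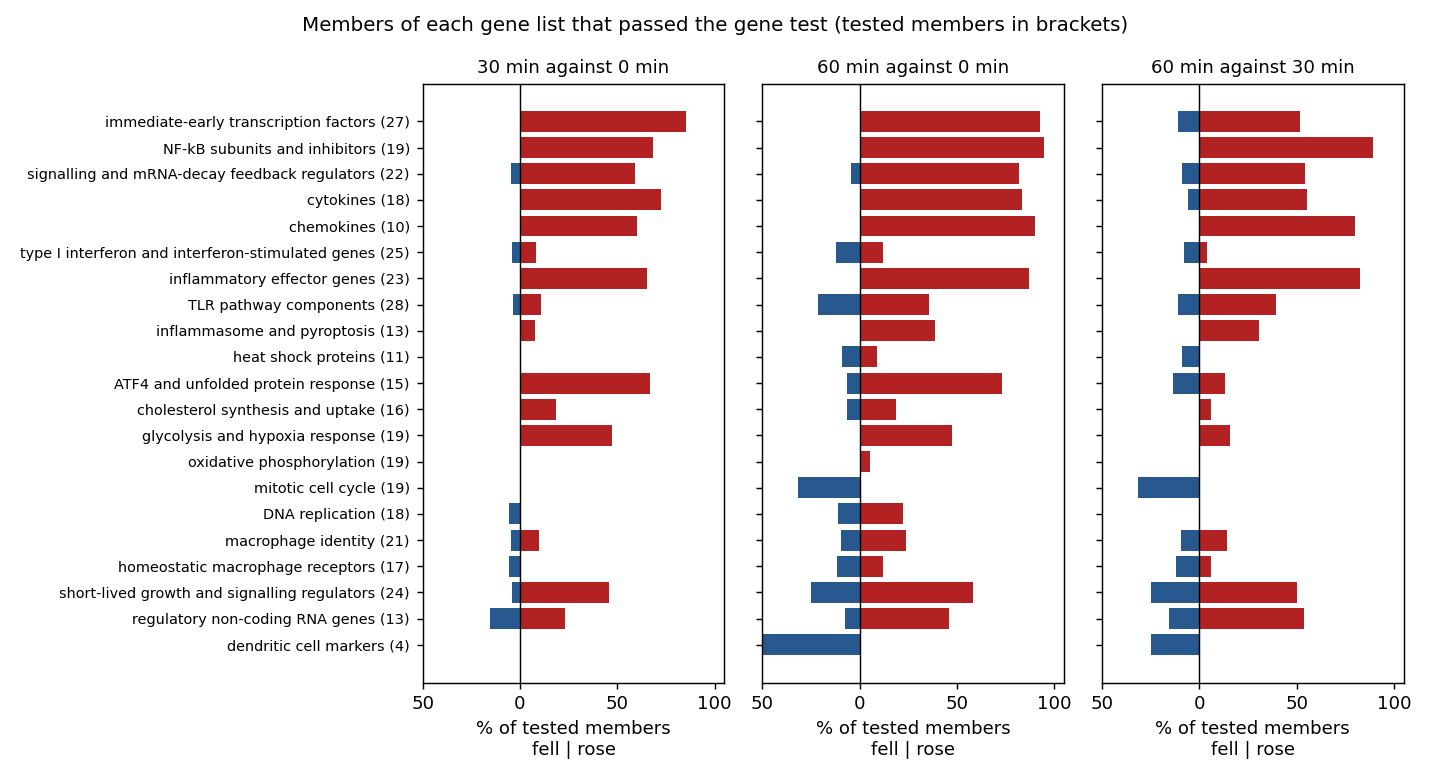
Bars give, for each fixed list with at least 3 tested members (their number in brackets), the percentage of tested members that rose (red, to the right) or fell (blue, to the left) by the edgeR gene test in each comparison. Of the 19 genes for NF-kB subunits and inhibitors, 13 rose at 30 min, 18 at 60 min and 17 from 30 to 60 min.

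The comparison of 60 min with 30 min tests whether the effects at the later and the earlier time differ. Acod1 rose a further 8.84-fold, from 15.2 ± 6.81 to 134 ± 13.4 CPM, the costimulatory receptor gene Cd40 5.74-fold, the cytokine gene Il1a 5.43-fold and the bacterial sensor gene Nod2 4.72-fold. In the other direction Fos fell 3.46-fold, from 197 ± 8.54 to 56.8 ± 13.2 CPM. The regulators of G-protein signalling Rgs1 and Rgs2 fell 2.86-fold and 2.4-fold, from 134 ± 13.8 to 46.7 ± 4.97 and from 64.2 ± 4.87 to 26.8 ± 2.98 CPM (SD, n = 3). Rgs1 thereby returned to a level close to its 45.6 CPM at 0 min.

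With edgeR, 1263 genes were higher and 1090 lower at 60 than at 30 min, 234 and 115 of them by at least 2-fold, of which 126 and 17 were protein-coding; other loci made up 46.2% and 85.2%. The median absolute log2 fold change was 0.42 and 0.31. Total counts as the only scaling gave 1005 higher and 1672 lower (37.5% higher, against 53.7% with TMM and 54.5% with DESeq2 size factors). Tested against a fold of 1.5, 186 genes were higher and 53 lower.

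Other large rises from 30 to 60 min were those of the phosphatase gene Dusp8 (6.51-fold), Traf1 (5.17-fold), Mir155hg (4.75-fold), Gadd45a, a growth arrest and DNA damage gene (4.59-fold), the transcriptional repressor gene Prdm1 (4.3-fold) and Saa3 (3.98-fold). For Acod1 (ENSMUSG00000022126.6, chromosome 14, 103046977 to 103056573, plus strand) the log2 change was 3.14 with SE 0.18 (edgeR adjusted p = 5.59e-08). The 30 min level of these genes was highest in replicate 1 for Acod1, at 23 CPM against 10.8 and 11.7 CPM, and the log2 change of Il1a was 3.04 without that library in place of 2.44. The remaining falls were those of Dusp6 (2.17-fold), Zswim3 (1.91-fold) and the small nuclear RNA gene Rnu1a1. The last stood at 23.1 ± 11.5 and 3.88 ± 5.47 CPM, and has near-identical copies. It lost its call (edgeR adjusted p = 0.0248) with DESeq2 (0.263) and without 30 min replicate 3 or 60 min replicate 1 or 2 (0.0571 to 0.108). Its log2 change of -2.56 was -4.95 without 60 min replicate 3 and -4.53 with limma-voom. Of the fixed genes Nfkbia (2.32-fold), Il1b (2.5-fold), Ccl4 (1.99-fold), Tnfaip3 (1.83-fold), Cxcl2 (1.79-fold), Tnf (1.64-fold), Ccl3 (1.36-fold) and Nos2 (3.51-fold) rose further. Ptgs2 rose 1.4-fold (edgeR adjusted p = 0.00908), a call lost with DESeq2 (0.117) and without 30 min replicate 2 (0.0543). Il6 (log2 change 0.5), Egr1 (0.04) and Tlr4 (-0.14) were not called, with edgeR adjusted p of 0.219, 0.978 and 0.052. Tlr4 was called with total counts as the only scaling (0.0207), with no filter on low counts (0.0192), with structural RNA genes removed (0.0472), with only the groups compared in the fit (0.0268) and without 0 min replicate 3 (0.0241) or 60 min replicate 1 (0.0393).

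**Figure D4:**
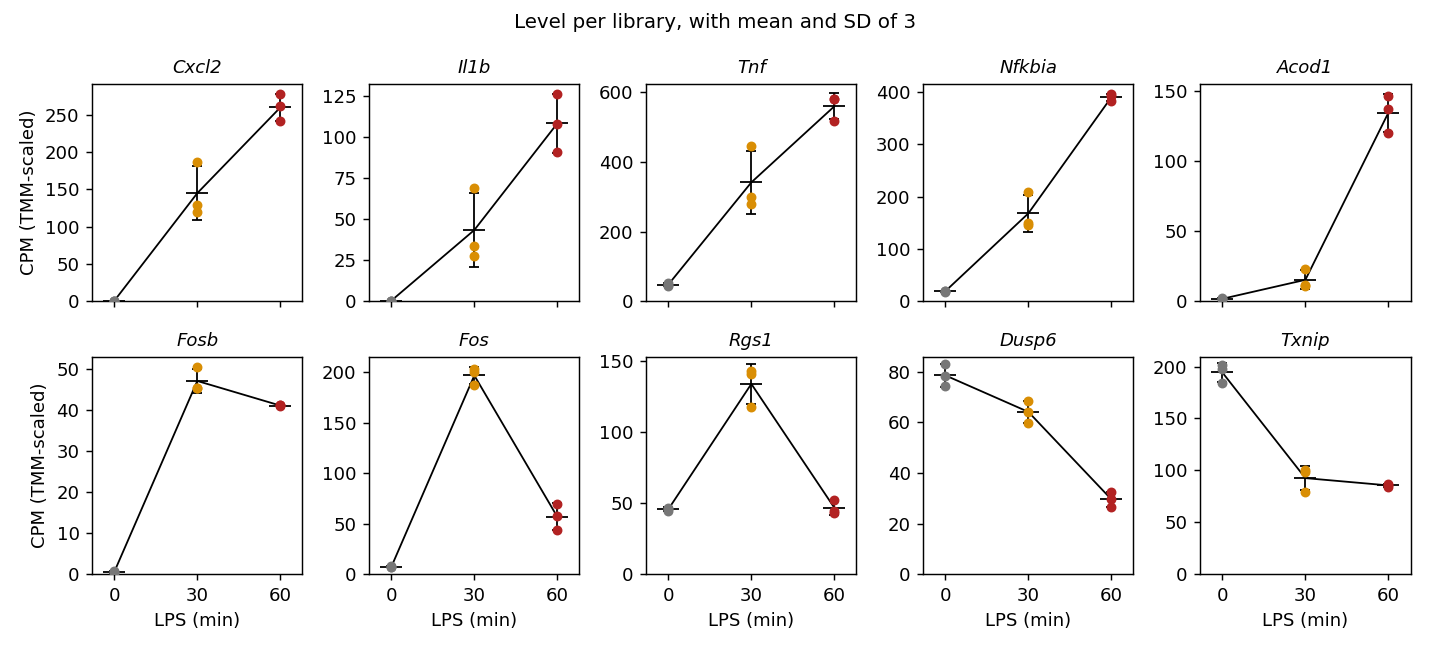
Points give the level of 10 genes in each library (CPM scaled by TMM factors, linear axes from 0) against minutes of LPS, with the mean and SD of 3 libraries joined by lines. Acod1 rose mainly after 30 min, Fos and Rgs1 were highest at 30 min, and Txnip fell by 30 min and Dusp6 mainly after it.

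Most members of the NF-kB list were higher at 60 than at 30 min. Of 19 genes 17 rose and 0 fell (17 and 0 adjusted over the list alone; camera adjusted p = 1.32e-52). Relb had a log2 change of 1.77, Tnip1 of 1.21, Nfkb1 of 0.95 and Rel of 0.83, and Tnip1 and Nfkb1 had not been called at 30 min against 0 min (edgeR adjusted p = 0.988 and 0.781). Of 23 inflammatory effector genes 19 rose and 0 fell (20 and 0 adjusted over the list alone; camera adjusted p = 1.03e-30), with Plau at 1.13 and Plaur at 0.64. Of 10 chemokine genes 8 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 7.88e-12), with Cxcl10 at 1.95. Of 18 cytokine genes 10 rose and Osm (-0.54) fell (11 and 1 adjusted over the list alone; camera adjusted p = 9e-09, and adjusted p = 0.0738 with an estimated correlation). Csf1 was at 1.69 and Il1rn, the interleukin-1 receptor antagonist, at 1.1. Of 22 feedback regulators 12 rose and 2 fell (14 and 2 adjusted over the list alone; camera adjusted p = 1.71e-14). Zc3h12c (1.44), Zc3h12a (1.28) and Dusp16 (1.45) were among the rises, and Dusp6 (-1.12) and Zfp36 (-0.67) were the falls. Immediate-early genes divided. Of 27, 14 rose and 3 fell (15 and 5 adjusted over the list alone; camera adjusted p = 0.00128, and adjusted p = 0.4 with an estimated correlation). The rises included Maff (1.54), Junb (0.73) and Klf6 (0.6), and the falls were Fos (-1.79), Klf2 (-0.72) and Ier2 (-0.67). Of 28 TLR pathway components 11 rose and 3 fell (11 and 6 adjusted over the list alone; camera adjusted p = 0.000677, and adjusted p = 0.0396 with an estimated correlation). Irak2 was at 1.3, Tlr2 at 0.99, Map3k8 at 0.97 and Ikbke at 0.92, and Ticam2 at -0.26. Of 24 short-lived growth and signalling regulators 12 rose and 6 fell (13 and 8 adjusted over the list alone; camera adjusted p = 0.00116, and adjusted p = 0.0447 with an estimated correlation). Gadd45a was at 2.2 and Pim1 at 1.09 beside Rgs2 at -1.26. Of 13 inflammasome genes 4 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.0143, adjusted p = 0.182 with an estimated correlation, and 0.0743 at a minimum count of 50). They were Casp4 (1.27), Nlrp3 (1.09), Ninj1 (0.27) and Mefv, from 14 counts to 89 (log2 change 2.6, and 3.46 without 30 min replicate 1). The mean was 0.37 and the median -0.02.

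The other lists were not called from 30 to 60 min by camera. Of 25 interferon genes 1 rose, Irf1 (1.27), and 2 fell, Stat2 (-0.68) and Irf8 (-0.21), with a list camera adjusted p of 0.809. Of 15 ATF4 and unfolded protein response genes 2 rose, Slc7a11 (0.94) and Herpud1 (0.36), and 2 fell, Xbp1 (-0.27) and Ddit3 (-0.39), with a list camera adjusted p of 0.259. Of 19 glycolysis genes 3 rose and 0 fell, including Pfkfb3 (0.37) and Slc2a1 (0.33), with a list camera adjusted p of 0.884. Of 13 regulatory non-coding RNA genes 7 rose and 2 fell, with Mir22hg at 0.94, Snhg12 at 0.6 and Neat1 at -0.47. The list camera adjusted p was 0.0951, and 0.0227 and 0.0173 without 30 min replicate 1 or 60 min replicate 3 and 0.0234 with no filter on low counts. Of 19 mitotic genes 0 rose and 6 fell, with Kif11 at -0.14. The list camera adjusted p was 0.0568, and 0.0253 and 0.0203 without 30 min or 60 min replicate 3, 0.00842 with total counts as the only scaling and 0.0259 with no filter on low counts. Of 21 macrophage identity genes 3 rose, Cebpb (0.42), Spi1 (0.15) and Csf1r (0.12), and 2 fell, Maf (-0.38) and Fcgr1 (-0.2), with a list camera adjusted p of 0.9. Of 17 homeostatic receptors 1 rose, Stab1 (0.63), and 2 fell, among them Trem2 (-0.14), with a list camera adjusted p of 0.904. The call of Trem2 was lost without 30 min replicate 3 or 60 min replicate 1 or 2. Of 11 heat shock proteins 0 rose and 1 fell, Hsph1 (-0.14), with a list camera adjusted p of 0.771. Of 16 cholesterol genes 1 rose, Srebf2 (0.11), with a list camera adjusted p of 0.336. The call of Srebf2 was lost without any single 60 min library, without 30 min replicate 1 (0.0993) or 2 (0.146) and with total counts as the only scaling (0.167). By fry the mitotic (adjusted p = 0.00973), cholesterol (0.0153), DNA replication (0.0199), dendritic cell (0.0381) and non-coding RNA (0.0411) lists were called. By edgeR 0 of 19 oxidative phosphorylation and 0 of 18 DNA replication genes were called (camera adjusted p = 0.992 and 0.71), with 0 higher and 0 lower, and 3 and 1, at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. Mcm3 (0.09) was called at a minimum count of 50 (0.0443) and Cdc6 (-0.11) with total counts as the only scaling (0.0211). The glycolysis gene Pfkp (-0.14, edgeR adjusted p = 0.0621) was called lower in 5 alternatives, among them DESeq2 (0.0439). With total counts as the only scaling Lss (0.0154), Sc5d (0.0262) and Stard4 (0.0276, and 0.0494 without 0 min replicate 2) were called lower. Ifi204 was called higher without 60 min replicate 2 (0.0188). Adjusted over the list alone, the counts were the same but for the glycolysis genes (4 higher and 1 lower) and the cholesterol genes (0 and 0).

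By camera 10 lists were higher and 0 lower at 30 min, 12 and 0 at 60 min, and 9 and 0 from 30 to 60 min. With an estimated correlation 8, 8 and 6 of the higher lists kept their calls. Their camera adjusted p then ran from 0.000354 to 0.0283 at 30 min, 0.00096 to 0.0153 at 60 min and 0.0132 to 0.0447 from 30 to 60 min. No list was called lower with the preset correlation, and at an unadjusted p under 0.05 there were 0, 0 and 1 lower lists, while at 60 min fry gave 2 lower lists and from 30 to 60 min 3.

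Sorted by course, 33 genes were transiently higher, 73 held higher, 95 growing higher and 129 late higher. The protein-coding genes among the 33 were Zfp36, Fos, Rgs1, Fabp4, Osm, Ier2, Klf2 and March4, with CPM means at 0, 30 and 60 min of 50.7, 500 and 314 for Zfp36 and 5.84, 66.2 and 45.4 for Osm. Protein-coding genes were 34 of the 73 held, 83 of the 95 growing and 74 of the 129 late genes; the late ones include Irak2, Ikbke, Casp4, Smad7 and Tnip1. On the lower side, where in simulated counts 2, 7, 0 and 2 other genes entered the classes, 25 genes were transient, 34 held, 0 growing and 75 late, of which 2, 7, 0 and 15 were protein-coding, with Txnip among the held and Zswim3 among the late. The growing lower class also held 0 genes with DESeq2 and limma-voom, and 1 with no filter on low counts.

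In the authors' deposited tables, at an adjusted p under 0.05, there were 549 genes higher and 329 lower at 30 min, 172 and 38 of them by at least 2-fold. At 60 min the authors' deposited table has 1490 and 1168, 392 and 135 of them by at least 2-fold. Of the calls in the authors' deposited table that could be matched by symbol, 822 of 874 (94.1%) at 30 min and 2622 of 2643 (99.2%) at 60 min were also called in that direction here, and 0 in the opposite one.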

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

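The tests of the splits of the libraries, of 30 min replicate 1, and of low counts at 60 min and from 30 to 60 min were chosen only after the results were seen. The tests of loci not annotated as protein-coding at 30 min were written before. The results below stand here because the effect at 60 min differs from that at 30 min in the direct test of 60 against 30 min, at an adjusted p under 0.05 by edgeR for genes and by camera for lists. Of 129 genes named by the rule for the comparisons with 0 min, 78 were called at 30 or 60 min and differed, 61 upward and 17 downward, and of 21 lists tested 9 differed. Values are log2 changes from 30 to 60 min.

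The larger upward differences were those of Acod1 (3.14), Mefv (2.6), Traf1 (2.37), Mir155hg (2.25), Gadd45a (2.2) and Saa3 (1.99). Next came Cd69 (1.95), Cxcl10 (1.95), Nos2 (1.81), Csf1 (1.69), Nr4a3 (1.55), Tnip3 (1.45) and Zc3h12c (1.44). Others were Nfkbiz (1.34), Il1b (1.32), Irak2 (1.3), Zc3h12a (1.28), Casp4 (1.27), Dusp5 (1.27), Irf1 (1.27) and Nfkbia (1.22). Id3 (1.17), Plau (1.13), Nlrp3 (1.09) and Pim1 (1.09) also lay above 1. Mefv, with 14 counts at 30 min, was at 3.46 without 30 min replicate 1.

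Between 0.5 and 1 were Ccl4 (0.99), Tlr2 (0.99), Map3k8 (0.97), Thbs1 (0.96), Clec4e (0.95), Nfkb1 (0.95), Tnfsf9 (0.95), Mir22hg (0.94) and Slc7a11 (0.94). The same holds for Ccrl2 (0.87), Tnfaip3 (0.87), Cxcl2 (0.84), Socs3 (0.82), Trib1 (0.74), Junb (0.73) and Tnf (0.71). Stab1 (0.63), Cd14 (0.61), Klf6 (0.6), Ccl2 (0.57) and Hist2h3c1 (0.51) complete this range. Smaller were Zfas1 (0.49), Ptgs2 (0.48), Ccl3 (0.44), Cebpb (0.42), Cdkn1a (0.4), Pfkfb3 (0.37), Herpud1 (0.36), Mir17hg (0.35) and Slc2a1 (0.33). The smallest were Ninj1 (0.27), Tlr9 (0.26), Snhg5 (0.25), Gas5 (0.17), Csf1r (0.12) and Srebf2 (0.11). Ptgs2 and Srebf2 lost their calls under alternatives named in the report.

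Downward differences were those of Fos (-1.79), Dusp6 (-1.12), Zswim3 (-0.93), Stat2 (-0.68), Zfp36 (-0.67), Osm (-0.54) and Neat1 (-0.47). Smaller were Maf (-0.38), Zbtb46 (-0.37), Ptgs2os2 (-0.3), Irf8 (-0.21), Trem2 (-0.14), Hsph1 (-0.14), Bub1b (-0.14), Aurka (-0.14), Cenpf (-0.13) and Plk1 (-0.11). Plk1 lost its call without 30 min replicate 2 or 3 or 60 min replicate 1 or 2 (adjusted p 0.0624 to 0.0959), and Cenpf without any of 5 libraries, namely 30 min replicates 1 and 2 and the 60 min libraries (0.063 to 0.141). Bub1b lost it without 60 min replicate 1 (0.0517).

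The lists, with their median, were the immediate-early factors (0.27), the NF-kB subunits and inhibitors (0.99), the feedback regulators (0.54), the cytokines (0.64), the chemokines (0.71) and the inflammatory effectors (1.01). The others were the TLR pathway components (0.02), the inflammasome genes (-0.02, with a mean of 0.37 and an upward test) and the short-lived growth and signalling regulators (0.2). Of these 9, the immediate-early factors, the cytokines and the inflammasome genes lost their call with an estimated correlation (adjusted p = 0.4, 0.0738 and 0.182).

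Other splits of the 6 libraries of a comparison were counted with these libraries alone in the fit. The time groups gave 1071 genes at 30 min, and the highest of the 9 other splits gave 1. At 60 min they gave 3297 and from 30 to 60 min 2375, where the highest other split gave 0. In each comparison 1 of 10 splits, the real one, gave as many genes. With 10 splits the share cannot fall under 0.05, so they are too few for this test.

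Of the 59 loci that fell at least 2-fold at 30 min, 50 were not annotated as protein-coding. Low counts alone, which give large folds by noise, are argued against at 30 min. There 1.7% of 2933 such loci fell this far, 2.17 times the highest share (0.784%) in 1000 draws of coding genes matched on level. The same holds from 30 to 60 min (3.34%, 3.16 times the highest share). It does not hold at 60 min against 0 min (4.4%, 1.43 times), short of the 1.5 times set for it. The draws were matched on mean CPM alone. Whether such loci differ from coding genes in spread between replicates or in shared reads was not tested. Unspliced transcripts of host genes counted in loci nested in their introns stay open: across 1036 loci nested on the same strand the change at 30 min went with the later change of the host from 30 to 60 min (rho = 0.337, permutation p = 1e-04, the smallest they can give), but 87 loci nested on the opposite strand gave 0.278, and the bootstrap interval of the difference, -0.135 to 0.272, spans 0. With the host's change at 30 min itself rho was 0.217 and -0.176, a difference not tested, and 27 of the loci that fell were nested on the same strand and 0 on the opposite one, which holds few loci. Loci that share a host gene were treated as independent, so the permutation p may be too small and the interval too narrow. The rule for the strands was made stricter after the values were seen, and a true fall of short-lived RNA was not tested apart from unspliced host transcripts.

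Replicate 1 of 30 min lay nearer the 60 min libraries than the other 30 min libraries did. Its differences from replicates 2 and 3 followed the step from the remaining library to 60 min (r = 0.26 and 0.31 over 9959 genes), and 73 of 75 genes called as growing without it were higher in it, with a median log2 difference of 0.48. A library further along the course should also be lower for genes that peak at 30 min, and one with a stronger response should be higher for them. Their median in it was -0.03 (17 genes, 8 above 0), against -0.11 and -0.03 in replicates 2 and 3. These 17 genes decide for neither, so a later stop and a stronger response cannot be told apart; the rule for the former was made stricter after the values were seen.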

How the results depend on the processing

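No test of this part was chosen after the results were seen. For the genes of the naming rule, 315 results were recomputed in 5643 runs under alternatives. In 5481 of these the result stayed on the same side of the threshold, in 116 the call was lost, in 46 a call was gained, and 0 were reversed. Direction was compared only where a result was called in the main fit or in the alternative, for genes and for lists. Of the 315 results 270 were the same in every run and 45 changed in at least 1. For the lists, 63 results gave 1134 runs: 1088 were the same, 12 lost and 34 gained a call, and 0 were reversed.

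A test against a fold of 1.5 asks for larger changes by its construction and gave 180 higher and 28 lower genes at 30 min, 430 and 102 at 60 min, and 186 and 53 from 30 to 60 min. Total counts as the only scaling gave 3048 lower genes at 60 min and 1672 from 30 to 60 min, and 1 list lower in each of these comparisons; the median of all genes moved by -0.07 and -0.04. The cause of the remaining shifts was not tested.

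With no filter on low counts, where more genes are tested, 757 genes were lower at 30 min, 121 of them by at least 2-fold. The classes then held 53 transiently higher, 50 transiently lower, 70 held lower and 1 growing lower genes, and 1 list was lower at 60 min and 1 from 30 to 60 min. A minimum count of 50, where fewer genes are tested, left 23, 76 and 59 genes lower by at least 2-fold in the 3 comparisons and 147 higher by that much from 30 to 60 min. It left 14 transiently lower, 43 held higher, 9 held lower, 83 late higher and 42 late lower genes. DESeq2 gave 21 held lower genes, and the cause was not tested. By fry 2 lists were lower at 60 min and 3 from 30 to 60 min; fry compares a list with no other genes by its construction.

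Replicate numbers were shared across times, but pairs with the same number (r = -0.06 to 0.01, 9 pairs) were no closer than others (-0.07 to 0.10, 18 pairs). With the number as a block, 588 genes were higher and 379 lower at 30 min, 1720 and 1514 at 60 min, and 1156 and 952 from 30 to 60 min, with 1 growing lower gene. Of these calls 952, 3189 and 2064 were shared with the 1166, 3562 and 2353 of the fit without it. Calls of Tlr9 at 30 min (adjusted p = 0.0569), Srebf2 at 30 min (0.0621), and Bag3 (0.069), Cox6a1 (0.0548) and Xcr1 (0.0524) at 60 min were not made with it, and those of Ndufv1 at 60 min (0.048) and of the inflammasome list at 30 min (0.0262) were. DESeq2 shared 911, 2835 and 1870 calls and limma-voom 1105, 3486 and 2284.

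Leaving out each library in turn gave 500 to 677 genes higher and 290 to 523 lower at 30 min, 179 to 206 and 46 to 66 by at least 2-fold. At 60 min the ranges were 1454 to 1848 and 1291 to 1640 (412 to 438 and 163 to 193 by at least 2-fold), and from 30 to 60 min 921 to 1338 and 730 to 1159 (194 to 272 and 100 to 118). The lower genes at 30 min were 290 without 0 min replicate 1, 310 without 30 min replicate 2 and 305 without 30 min replicate 3. Higher classes held 25 to 34 transient, 59 to 89 held, 86 to 90 growing and 113 to 157 late genes, and lower classes 17 to 24, 26 to 49, 0 to 0 and 65 to 78. Lists higher were 9 to 12, 11 to 12 and 9 to 10. Lists lower were 0 to 1 at 60 min, with 1 without 60 min replicate 3, and 0 to 1 from 30 to 60 min, with 1 without 30 min replicate 3 or 60 min replicate 3. Fewer libraries also lower the power of the test by construction.

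Depth limits the genes near the filter: of the genes lower by at least 2-fold, 54.2%, 50% and 40% in the 3 comparisons had a mean under 1 CPM, where 10 counts are 0.35 CPM.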

Other observations

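The gene families below and the test of base composition were chosen only after the results were seen; the tests of gene span and of ATTTA motifs were written before.

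Genes for snoRNA hosts, replication-dependent histones and zinc finger proteins were picked after a look through 299 families of at least 6 genes with a shared symbol stem or function, tested by camera and adjusted over these families. None of their calls held with an estimated correlation in place of the preset. The snoRNA host Gas5 and its relative Snhg12 also belong to the fixed list of regulatory non-coding RNA genes. Of 15 snoRNA host genes, whose introns carry small nucleolar RNAs, 0 rose and 6 fell at 30 min (median log2 change -0.15, adjusted p = 1.67e-05, and adjusted p = 0.997 with an estimated correlation). From 30 to 60 min 9 rose and 0 fell (0.24, adjusted p = 0.00445, and adjusted p = 0.999 with an estimated correlation). At 60 min against 0 min 3 rose and 4 fell (-0.09, adjusted p = 0.998). Gas5 went from 182 to 128 and 143 CPM, Zfas1 from 85.1 to 49.2 and 69.1 CPM, and Snhg12 from 21 to 14.6 and 22.1 CPM at 0, 30 and 60 min.

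Of 64 replication-dependent histone genes 14 rose and 1 fell at 30 min (median 0.17, adjusted p = 0.0045, and adjusted p = 0.997 with an estimated correlation). At 60 min 0 rose and 31 fell (-0.17, adjusted p = 0.000147), and from 30 to 60 min 1 rose and 49 fell (-0.33, adjusted p = 2.03e-23), each with adjusted p = 0.999 with an estimated correlation. Hist1h3g went from 151 to 157 and 106 CPM and Hist1h3f from 143 to 171 and 126 CPM. These genes are near-identical copies without poly(A) tails, so the share of reads given to each copy is uncertain. Of 328 genes with a Zfp symbol 12 rose and 33 fell at 30 min (-0.1, adjusted p = 0.00308, and adjusted p = 0.219 with an estimated correlation). At 60 min 27 rose and 129 fell (-0.19, adjusted p = 0.000365, and adjusted p = 0.197 with an estimated correlation), and from 30 to 60 min 21 rose and 46 fell (-0.08, adjusted p = 0.156). The medians of the 3 families had the same sign with DESeq2 size factors and with total counts as the only scaling.

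Genes called higher first at 60 min were longer than those higher at 30 min. The 74 late protein-coding genes had a median genomic span of 28.2 kb, 3.44 times the 8.2 kb of the 125 coding genes at least 2-fold higher at 30 min (permutation p = 1e-05, the smallest they can give). All coding genes tested had a median of 23.3 kb, and transient, held and growing genes 3.98, 7.45 and 9.34 kb. A candidate explanation is that longer units take longer to transcribe to their end; short genes picked for early induction would give the same ratio, and transcription itself was not measured.

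Transcripts that rose early carried more ATTTA motifs, which mark AU-rich elements of unstable mRNAs. In 124 of the 125 coding genes at least 2-fold higher at 30 min a 3' untranslated region was annotated, with a mean of 3.54 motifs per kb, where 1000 draws of coding genes matched on level had a median of 1.68 and a highest value of 2.38. Late genes had 1.88, with 1.54 and 2.51 in their draws. In all draws the level matched was the mean CPM over the 9 libraries, which includes the rise itself. The level at 0 min and the length of the 3' untranslated region were not matched. The other 9 arrangements of the bases of ATTTA were also frequent, at 18 per kb. For these the draws had a median of 14.1 and a highest value of 18.2, so base composition may contribute. As the whole cause it is argued against, since the ratio of ATTTA to these arrangements was 0.197, where the draws had a median of 0.121 and a highest value of 0.159. Fast-induced transcripts in these cells may thus share a motif of rapid decay; decay was not measured.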
